A study of Arabidopsis thaliana with 24 samples.

How the data were processed

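Total RNA from roots and leaves of Arabidopsis thaliana was measured on 24 Affymetrix ATH1 arrays. The plants were wild type (Col) or the double mutant rglg1 rglg2, called the mutant here, and were kept at 21 °C in continuous light. At 10 days of age they were moved for 3 days to medium with 40 µM FeEDTA (+Fe) or to medium with 100 µM of a ferrozine-type iron chelator (-Fe), and they were 13 days old at harvest. Each of the 8 groups of tissue, genotype and medium held 3 arrays, which the labels call biological replicates. RNA was extracted with Trizol and hybridised as biotinylated cRNA.

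The values come from the deposited table of the series and were read as log2 signal per probe set. RMA is named in the submitters' processing notes, without a version. In addition, the median over the 24 arrays was 0 within 1e-05 for all 17854 probe sets in the table. Each value is therefore relative to the other arrays, and no absolute signal level can be read from it. Which arrays were normalized together, how the probe sets in the table were chosen, and when the centring was done are not given in the sources used here. Values ranged from -5.76 to 7.86. The median of an array's values lay between -0.136 and 0.049. For arrays, the number of arrays limits the precision, and no counting interval applies.

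Of the 17854 probe sets, 44 controls were left out, and 17810 were tested. A single gene was named for 9869 of them, several genes for 353 and no gene for 7588. Names came from the platform's gene IDs, of which 9822 matched the reference annotation (TAIR10.1, used only for names) and 47 did not. For 8 of the 54 measured list genes the reference holds only the locus code, and the symbols are those of the gene lists, which were not checked against a source. They are S8H (AT3G12900), BTSL1 (AT1G74770), BTSL2 (AT1G18910), IMA1 (AT1G47400), MTP8 (AT3G58060), COSY (AT1G28680), HSP17.6C (AT1G53540) and RGLG5 (AT1G67800). In all, 9726 loci were named, and 93 of them by more than 1 probe set. Probe sets without a single named gene count in all totals, but are not given a gene. All 24 columns were matched to their samples by their labels, and 0 were left unmatched. No probe set with a single named gene stood for RGLG1 or RGLG2, so their transcripts were not analysed here. Whether any unnamed probe set that was lower in the mutant measures either of these genes was not tested; if so, its fall is that of a mutated gene itself.

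Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with 1 mean per group. Each tissue was fitted on its own 12 arrays, with 8 residual degrees of freedom. The comparison of the iron response between tissues used all 24 arrays in 1 fit. P-values were adjusted by the Benjamini-Hochberg method over the 17810 probe sets within each comparison. A probe set was called changed at an adjusted p under 0.05, with no minimum fold. All tests were two-sided. The 11 comparisons were the iron response (-Fe minus +Fe) in each genotype and tissue, the difference between genotypes (mutant minus Col) on each medium in each tissue, the genotype by iron interaction in each tissue, and the tissue by iron interaction in Col. Errors beside a log2 change are the moderated standard error of limma. Those beside a group mean are the SD of 3 arrays.

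Genes were named in the text by a rule. For an iron response these were the 10 probe sets with the largest rise and the 10 with the largest fall among those called, with a single named gene and with all 3 arrays of 1 medium on the same side of all 3 of the other. Chance gives such a separation to 10% of probe sets with 3 arrays against 3. For an interaction or a genotype difference, the rule took the 10 largest called changes in each direction. Where fewer than 3 passed, it took the 5 smallest p-values, given as values and not as calls. Members of the gene lists were named as well, where they were needed for a count. The text gives the part of these genes that best describes each comparison.

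The 22 gene lists held 352 loci, of which 54 were measured and named. Measured here means that a probe set named that gene alone, so other genes may lie on unnamed probe sets. Measured genes were 5 of 20 for iron acquisition, 7 of 18 for iron regulators and 5 of 15 for phenylpropanoids and coumarins. They were 8 of 48 for photosynthesis, 7 of 25 for tetrapyrrole synthesis, 6 of 15 for auxin and 3 of 21 for abscisic acid. Some lists, such as iron distribution and iron storage, had none. Lists with at least 3 measured loci were tested as sets with camera at a preset correlation of 0.01 and, as an alternative, with the correlation estimated from the data. These were 8 lists in 11 comparisons, adjusted together over 88 tests. A locus with several probe sets entered as their mean. The plan had been to use the probe set with the highest mean, but on centred values that mean carries no signal level. The comparisons, the naming rule, the gene lists and the alternative fits were fixed before the data were examined. After the data were seen, 13 gene families were added, defined by symbol or by plastid encoding, with at least 8 measured loci each and 143 tests.

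Overlaps between comparisons were counted as probe sets called in both, in the same direction, against the number that independent calls would give. Correlations between comparisons are across probe sets, which are not independent replicates.

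Alternatives were replicate number as a block, a fit with other sets of arrays, quantile normalization, centring of each array on its median, a variance prior with trend and robust settings, array weights, and leaving out each array in turn. After the data were seen, a block for replicate number within each genotype and a fit without replicate 3 of the mutant leaves on both media were added. Pairing by replicate number was checked with the correlation, across probe sets, between the deviations of equally numbered arrays from their group means. Numbers were taken to pair the arrays of a comparison where all 3 correlations were above 0.1. This held only for the mutant leaf iron response (0.39, 0.44 and 0.6). Its counts with the replicate block and with the block within genotype are given beside the main one.

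The pipeline was tested on simulated data with 100 changed probe sets at each of 2 sizes among 17810. Values were drawn independently for each probe set and array, so the simulation held no correlation between genes and no outlying replicate. At a log2 change of 1, the root iron response recovered 100% of them and the leaf iron response 90%. The interaction recovered 91% in roots and 65% in leaves, and the leaf genotype difference on +Fe 88%. At a log2 change of 2, these comparisons recovered between 94% and 100%. False calls made up between 2.05% and 8.62% of all calls. With camera, 100% of the shifted lists of 6 genes and 2.7% of the unshifted ones had an unadjusted p under 0.05. As the simulated genes were not correlated, this does not give the rate for lists of correlated genes. Figures were drawn with matplotlib 3.10.9.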

Results

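The series measured transcripts in roots and leaves of Col and of rglg1 rglg2, a double mutant in genes for RING-domain ubiquitin ligases, on medium with iron (+Fe) or with an iron chelator in its place (-Fe). There were 24 arrays in 8 groups of 3 biological replicates, and 17810 probe sets were tested. Values are log2 signals centred per probe set, so only differences between arrays are reported. Within groups, replicates correlated across probe sets at r = 0.933 to 0.984 in roots and 0.944 to 0.971 in Col leaves. In mutant leaves, replicates 1 and 2 correlated at 0.967 on +Fe and 0.956 on -Fe, whereas pairs with replicate 3 gave 0.852 to 0.905. On the main axis of variation among leaf arrays (53.1% of variance), replicate 3 of the mutant lay at -0.8 on +Fe and 2.1 on -Fe. The other mutant leaf arrays lay at 33.9 to 51 and the Col leaf arrays at -41.6 to -11.2. On the second leaf axis (13% of variance), mutant -Fe replicate 3 lay at 5.5. The other -Fe leaf arrays lay at -24.8 to -12.1 there, and the +Fe leaf arrays at 11.9 to 18.5. In roots, on the axis with 25.1% of variance, replicate 3 lay nearest to the other genotype in each group. In the mutant it was at -11 on +Fe (others -25.3 and -26.1) and -4.7 on -Fe (others -7.3 and -6.3). In Col it was at 5.8 on +Fe (others 16.9 and 12.7) and 11.7 on -Fe (others 16.4 and 17.2).

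**Figure D1:**
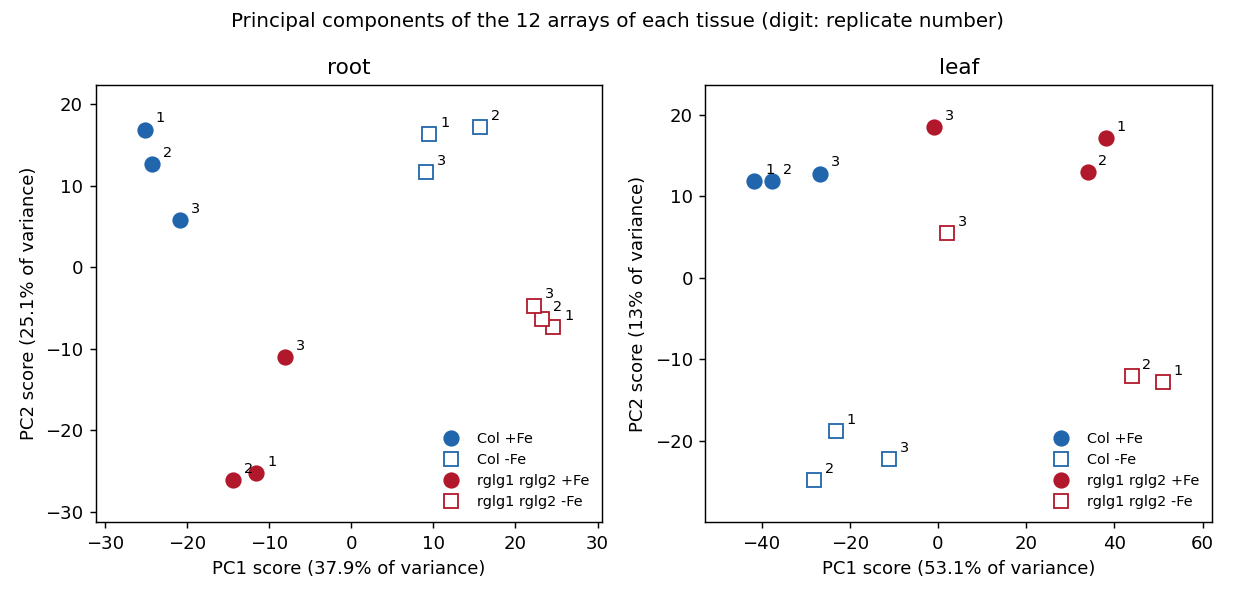
Principal components of the 12 root arrays and the 12 leaf arrays, with the share of variance on each axis and the replicate number beside each point. Replicate 3 of the mutant leaves lies at -0.8 (+Fe) and 2.1 (-Fe) on the leaf PC1, between the other mutant arrays (33.9 to 51) and Col (-41.6 to -11.2). Its -Fe array lies at 5.5 on the leaf PC2, between the other -Fe arrays (-24.8 to -12.1) and the +Fe arrays (11.9 to 18.5).

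The iron response of Col roots addressed which transcripts change when wild-type roots lose access to iron. S8H (AT3G12900), which makes the coumarin fraxetin, was 35.5-fold higher on -Fe, a log2 change of 5.15 ± 0.16 (SE, n = 3 per group, adjusted p = 2.87e-11). MTP8 (AT3G58060), a manganese transporter, rose 17-fold (log2 4.09 ± 0.12). The transcription factor gene BHLH101 (AT5G04150) rose 15.8-fold (log2 3.98 ± 0.18), and IMA1 (AT1G47400), which encodes an iron-responsive peptide, rose 14.2-fold (log2 3.83 ± 0.21). The largest fall among named genes was that of AT1G52820, of the 2-oxoglutarate-dependent oxygenase family, with a log2 change of -3.33 ± 0.24. AT3G13840, a GRAS family gene, fell by 2.18 ± 0.18 and AT3G49160, of the pyruvate kinase family, fell by 1.87 ± 0.14. The sugar transporter gene SWEET2 fell by 1.33 ± 0.21. The unnamed probe set 253502_at rose by 6.95 ± 0.23.

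All 5 measured genes of the iron acquisition list rose in Col roots, and all 5 also when adjusted over the list alone. They were S8H, BGLU42 (log2 2.5 ± 0.14), BTSL1 (2.15 ± 0.19), F6'H1 (1.69 ± 0.1) and BTSL2 (1.19 ± 0.12). BTSL1 and BTSL2 encode ubiquitin ligases of the iron response, and F6'H1 acts ahead of S8H in coumarin synthesis. The list moved up as a set (camera, adjusted p = 1.6e-17, and adjusted p = 0.0088 with an estimated correlation). Of 5 measured phenylpropanoid and coumarin genes, 4 rose, and 4 when adjusted over the list alone; S8H, BGLU42 and F6'H1 belong to both lists, and HCT rose by 0.46 ± 0.08. This list also moved up (adjusted p = 1.2e-12, and adjusted p = 0.033 with an estimated correlation). Of 7 measured iron regulators, BHLH101, IMA1 and PYE (1.3 ± 0.09) rose, 5 rose when adjusted over the list alone, and the list moved up (adjusted p = 1e-08, and adjusted p = 0.0088 with an estimated correlation). Of 8 measured photosynthesis genes, 6 fell, among them RCA (-0.97 ± 0.15), PSAN (-0.9 ± 0.13) and PSBY (-0.76 ± 0.11). All 8 fell when adjusted over the list alone. The list moved down at adjusted p = 4.4e-10, a call lost with adjusted p = 0.081 with an estimated correlation. This list had also been set as a marker of green tissue in root samples. Of 3 measured genes of the abscisic acid and dehydration list, COR15A and COR47 fell, by 0.43 ± 0.11 and 0.43 ± 0.1, and 2 fell when adjusted over the list alone (camera, adjusted p = 0.057).

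With limma, 921 probe sets changed in Col roots, of which 392 rose and 529 fell. A log2 change of at least 1 was reached by 105 that rose and 55 that fell. The count was 602 with only the 6 arrays compared in the fit, 1578 with array weights, and 612 without Col -Fe replicate 2.

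In mutant roots the same comparison asked how the double mutant responds to iron loss. S8H rose 52.6-fold (log2 5.72 ± 0.16, n = 3 per group, adjusted p = 9.53e-12), MTP8 20.6-fold (log2 4.37 ± 0.12), BHLH101 9.2-fold (log2 3.2 ± 0.18) and IMA1 6.55-fold (log2 2.71 ± 0.21). AT1G52820 fell by 2.51 ± 0.24, AT3G13840 by 2.05 ± 0.18 and AT3G49160 by 1.34 ± 0.14 in log2. All 5 iron acquisition genes rose, and all 5 phenylpropanoid and coumarin genes, here with COSY (0.47 ± 0.12), which acts in coumarin closure. Adjusted over the list alone, the counts were also 5 and 5. As sets they moved up with adjusted p = 2.3e-15 and 8.2e-13, and with adjusted p = 0.0097 and 0.033 with an estimated correlation. BHLH101, IMA1 and PYE (1.11 ± 0.09) were the 3 of 7 iron regulators that rose, and 3 when adjusted over the list alone (set shift at adjusted p = 0.00032, and adjusted p = 0.033 with an estimated correlation). Of the 8 photosynthesis genes 6 fell, with PSAN at -0.95 ± 0.13 and PSAE1 at -0.89 ± 0.14, and 7 when adjusted over the list alone. Their shift down at adjusted p = 6.7e-08 was lost at adjusted p = 0.13 with an estimated correlation. COR15A and COR47 fell again, by 0.42 ± 0.11 and 0.37 ± 0.1, which made 2 of 3 in the abscisic acid and dehydration list, and 2 when adjusted over the list alone.

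In total 1266 probe sets changed in mutant roots, 511 up and 755 down. The count was 3315 without mutant +Fe replicate 3, 614 and 601 without mutant +Fe replicates 1 and 2, 618, 592 and 648 without mutant -Fe replicates 1, 2 and 3, and 5097 with array weights. The difference of 5′ and 3′ control probe sets moved with this comparison, from 0.02 ± 0.16 (SD) on +Fe to 0.23 ± 0.03 on -Fe, against 0.22 ± 0.1 and 0.19 ± 0.12 in Col roots, and so also with the root interaction.

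The responses of the genotypes in roots shared 259 probe sets that rose, against 11.2 for independent calls, and 259 that fell, against 22.4. Another 5 were called in opposite directions. Across all probe sets the 2 responses correlated at r = 0.72 (Spearman's rho 0.43). Of the 1664 probe sets called in either genotype, 93.3% changed with the same sign.

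**Figure D2:**
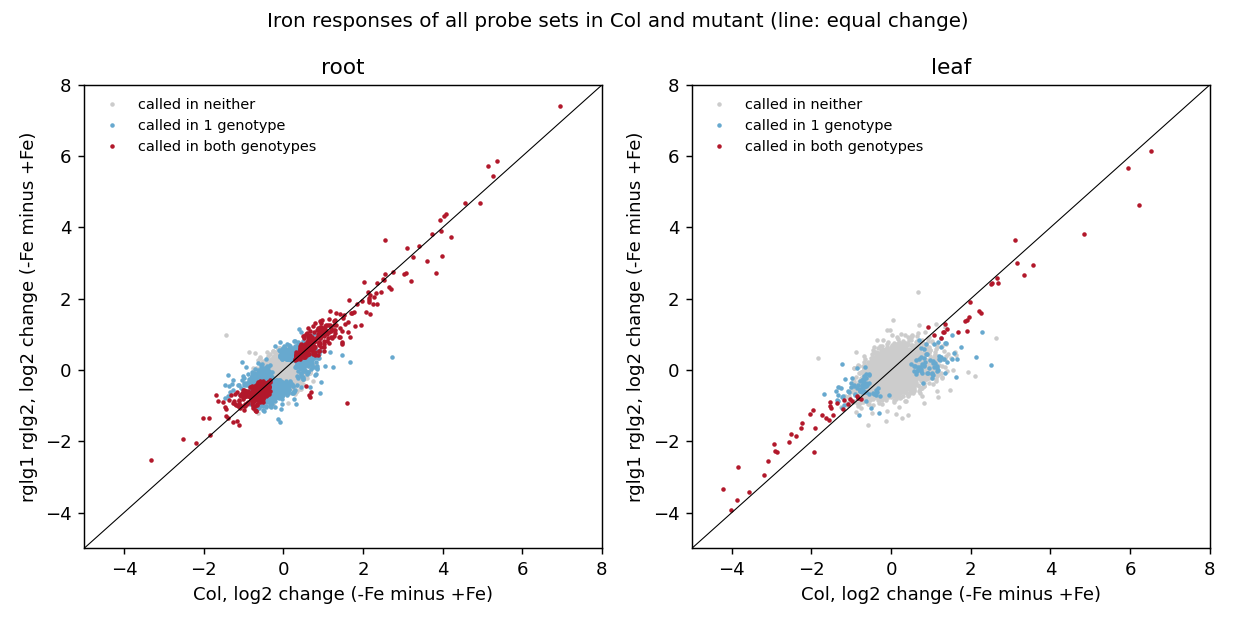
Log2 change on -Fe in Col (horizontal) and in the mutant (vertical) for 17810 probe sets in roots and leaves, coloured by the number of genotypes in which the probe set was called. In roots 259 probe sets rose and 259 fell in both genotypes, and in leaves 27 rose and 35 fell in both.

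The genotype by iron interaction tested directly whether the iron response of roots differed between genotypes. It called 3 named genes, all with a more negative response in the mutant. AT1G65500 rose by 1.59 ± 0.21 in Col and fell by 0.91 ± 0.21 in the mutant, an interaction of -2.5 ± 0.3 (adjusted p = 0.0118). AT4G15690, of the glutaredoxin family, had an interaction of -1.44 ± 0.21 (adjusted p = 0.0496) and AT3G46880 of -1.31 ± 0.18 (adjusted p = 0.0376). Both rose in Col (0.68 ± 0.15 and 0.7 ± 0.13) and fell in the mutant (-0.76 ± 0.15 and -0.61 ± 0.13). The iron regulator list moved down as a set (camera, adjusted p = 0.0014, and adjusted p = 0.044 with an estimated correlation). None of its 7 genes was called over all probe sets, and 2 were when adjusted over the list alone, IMA1 at -1.12 ± 0.3 and BHLH101 at -0.78 ± 0.26. On +Fe, IMA1 in mutant replicate 3 (-1.92) lay near Col replicate 3 (-2.01), apart from mutant replicates 1 and 2 (-1.18 and -1.12). The list test was not repeated with single arrays left out, so whether the shift rests on single arrays was not tested. On the values as given, no other of the 8 lists moved; after quantile normalization the tetrapyrrole list moved up (adjusted p = 0.046, and 0.13 as given).

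The interaction count of 3 became 393 with array weights and 387 without mutant +Fe replicate 3. It was 1 without Col +Fe replicates 1 or 2, Col -Fe replicate 1 or mutant -Fe replicate 2, 0 without mutant +Fe replicates 1 or 2 or mutant -Fe replicate 3, 6 without Col -Fe replicate 3, and 7 with a block for number within genotype. AT1G65500 lost its call without mutant +Fe replicates 1 or 2 (adjusted p = 0.0788 and 0.0918) or mutant -Fe replicate 3 (0.0595), over a range of values from -2.47 to -2.4. AT4G15690 kept its call only without Col +Fe replicate 3, Col -Fe replicate 2 or mutant +Fe replicate 3, and AT3G46880 only without those or mutant -Fe replicate 1; otherwise adjusted p reached up to 0.249 and 0.172.

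The genotype difference in roots on +Fe asked what the loss of both ligases changes when iron is supplied. AT1G65500 was 6.86-fold higher in the mutant (log2 2.78 ± 0.21, n = 3 per group, adjusted p = 5.63e-06) and AT4G33720, a gene of the PR-1-like family, 6.44-fold higher (log2 2.69 ± 0.36). IMA1 was higher by 1 ± 0.21, the only call among 7 iron regulators, of which 2 were higher and 1 lower when adjusted over the list alone. Its values in replicates 1, 2 and 3 were -1.18, -1.12 and -1.92 in the mutant and -2.55, -2.67 and -2.01 in Col. Replicate 3 of the mutant thus lay near that of Col. AT5G26270 was lower by 4.9-fold (log2 -2.29 ± 0.16), GH9B13, an endoglucanase-family gene, by 2.51-fold (log2 -1.33 ± 0.11) and the MADS-box gene AGL19 by 2.47-fold (log2 -1.31 ± 0.15). The unnamed probe sets 259178_at and 250177_at were lower by 12.6-fold and 7.5-fold, with log2 changes of -3.65 ± 0.15 and -2.91 ± 0.16. The chlorophyll synthesis gene CHLM was lower by 0.61 ± 0.12, and was the 1 call among 7 tetrapyrrole genes, also when adjusted over the list alone. No list moved as a set.

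In all 1913 probe sets differed, 1014 higher and 899 lower in the mutant. A difference of control probe sets for RNA 5′ and 3′ ends (5 of each) averaged 0.02 ± 0.16 (SD) in mutant roots on +Fe and 0.22 ± 0.1 in Col roots on +Fe; in mutant +Fe replicate 3 it was 0.19. The count was 3758 without mutant +Fe replicate 3, 728 and 889 without mutant +Fe replicates 1 and 2, 832 and 1158 without Col +Fe replicates 1 and 2, 812 with only the 6 arrays compared, and 5634 with array weights.

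On -Fe, AT4G33720 was 9.33-fold higher in mutant roots (log2 3.22 ± 0.36, n = 3 per group, adjusted p = 0.000244). AT5G06730, a peroxidase family gene, was higher by 1.52 ± 0.1. AT5G26270 was lower by 8.83-fold (log2 -3.14 ± 0.16, adjusted p = 8.35e-08), ATGSTF13, a glutathione transferase gene, by 2.62-fold (log2 -1.39 ± 0.1) and AGL19 by 2.76-fold (log2 -1.46 ± 0.15). S8H was higher by 0.71 ± 0.16, the only call in the iron acquisition list and in the phenylpropanoid and coumarin list, also when adjusted over each list alone. BHLH101 was lower by 0.82 ± 0.18, the only call among 7 iron regulators, and 2 were lower when adjusted over the list alone. The phenylpropanoid and coumarin list moved up (adjusted p = 0.022, lost at adjusted p = 0.4 with an estimated correlation, and 0.057 after quantile normalization). The abscisic acid and dehydration list moved down (adjusted p = 0.022, lost at adjusted p = 0.24 with an estimated correlation), with COR15A lower by 0.42 ± 0.11 and 3 of 3 lower when adjusted over the list alone.

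In all 693 probe sets differed on -Fe, 323 higher and 370 lower. With the 6 arrays alone the count was 1106 and with array weights 1921; without mutant -Fe replicates 1, 2 and 3 it was 257, 289 and 337, and without Col -Fe replicates 1 and 3 it was 355 and 453. The differences on +Fe and -Fe shared 227 probe sets that were higher, against 18.4 for independent calls, and 213 that were lower, against 18.7.

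The iron response of Col leaves addressed the same question in the shoot. BHLH101 rose 75.4-fold (log2 6.24 ± 0.3, n = 3 per group, adjusted p = 1.53e-07) and IMA1 62.1-fold (log2 5.96 ± 0.36). AT4G36700, a cupin family gene, rose 28.5-fold (log2 4.83 ± 0.53) and AT3G02480, of the late embryogenesis abundant family, 11.9-fold (log2 3.57 ± 0.29). SAPX, the stromal ascorbate peroxidase, which carries heme, fell by 2.95 ± 0.21. AT3G49160 fell by 3.56 ± 0.21 and AT3G43670, a copper amine oxidase family gene, fell by 2.86 ± 0.13. The unnamed probe set 251677_at rose by 6.52 ± 0.14.

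**Figure D3:**
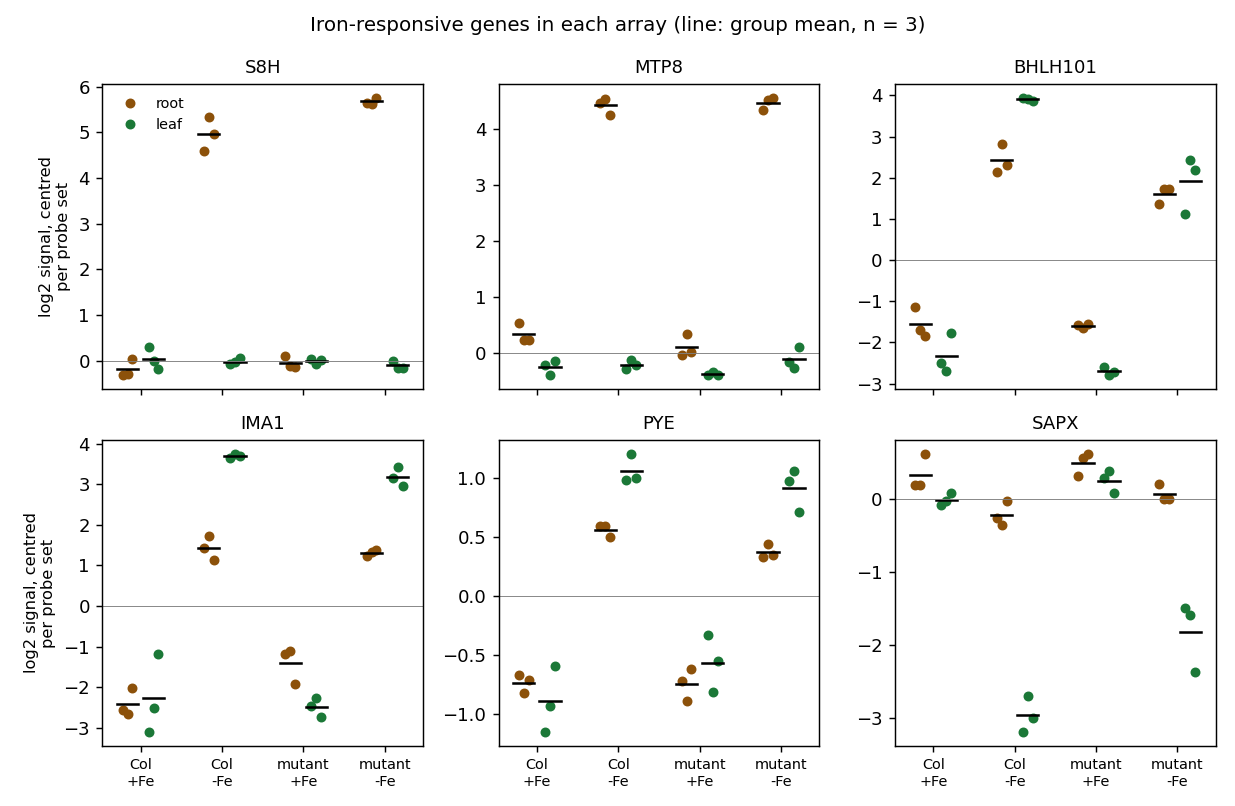
Centred log2 signal of 6 iron-responsive genes in each of the 24 arrays, by genotype and medium (roots brown, leaves green, line at the mean of 3 arrays). S8H lies at 4.58 to 5.76 in the -Fe root arrays and at -0.15 to 0.05 in the -Fe leaf arrays, whereas IMA1 lies at 1.12 or above in all -Fe arrays.

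BHLH101, IMA1 and PYE (1.95 ± 0.17) were the 3 of 7 iron regulators that rose in Col leaves, and 3 when adjusted over the list alone. The list moved up (adjusted p = 1.3e-06, and adjusted p = 0.034 with an estimated correlation). BTSL1 was the 1 of 5 iron acquisition genes that rose (1.48 ± 0.12 as the mean of 2 probe sets, at 0.72 with adjusted p = 0.0513 and 2.25 with adjusted p = 4.33e-06), and 3 rose when adjusted over the list alone. That list moved up at adjusted p = 0.0078, lost at adjusted p = 0.24 with an estimated correlation and at 0.051 with 1 probe set per locus. PSAN (-1.19 ± 0.19) was the 1 of 8 photosynthesis genes that fell, and 3 fell when adjusted over the list alone. The list moved down at adjusted p = 0.00033, lost at adjusted p = 0.28 with an estimated correlation. In the auxin list, 3 of 6 genes rose and 1 fell when adjusted over the list alone, and none was called over all probe sets. Its shift up at adjusted p = 0.044 was lost at adjusted p = 0.29 with an estimated correlation.

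In Col leaves 184 probe sets changed, 91 up and 93 down. The count was 110, 98 and 111 without Col +Fe replicates 1, 2 and 3, and 117 and 90 without Col -Fe replicates 1 and 3. It was 319 with the 6 Col arrays alone, 766 with array weights, 539 with a block for number within genotype and 565 without replicate 3 of the mutant leaves, which share the fit.

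In mutant leaves IMA1 rose 50.7-fold (log2 5.66 ± 0.36, n = 3 per group, adjusted p = 2.5e-06), BHLH101 24.6-fold (log2 4.62 ± 0.3) and AT4G36700 14-fold (log2 3.81 ± 0.53). AT3G49160 fell by 3.42 ± 0.21, AT3G43670 by 2.3 ± 0.13 and SAPX by 2.06 ± 0.21. PYE rose by 1.48 ± 0.17, and with BHLH101 and IMA1 made up the 3 of 7 iron regulators that rose, also when adjusted over the list alone. That list moved up (adjusted p = 1.3e-08, and adjusted p = 0.025 with an estimated correlation). BTSL1 was the 1 call among 5 iron acquisition genes, also when adjusted over the list alone, at 0.78 ± 0.12 as the mean of 2 probe sets that differed, with 1.6 (adjusted p = 0.000177) and -0.04 (adjusted p = 0.971). That list did not move (adjusted p = 0.078 on the values as given, and 0.81 with 1 probe set per locus). HEME1, a uroporphyrinogen decarboxylase gene, fell by 0.73 ± 0.14, the 1 call among 7 tetrapyrrole genes, and 5 fell when adjusted over the list alone. The tetrapyrrole list moved down at adjusted p = 7e-06, lost at adjusted p = 0.15 with an estimated correlation. The photosynthesis list had 0 genes called by limma and 2 that fell when adjusted over the list alone. Its shift down at adjusted p = 0.0018 was lost at adjusted p = 0.29 with an estimated correlation and at 0.064 after quantile normalization.

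In mutant leaves 76 probe sets changed, 28 up and 48 down. With replicate number as a block, shared by both genotypes, the count was 68. Deviations of equally numbered leaf arrays correlated at -0.29 to 0.04 between genotypes, so the shared block may not remove the pairing within the mutant. With a block for number within genotype the count was 113, 45 up and 68 down. It was 166 without mutant -Fe replicate 3, 50 without mutant -Fe replicate 2, 38 with the 6 mutant arrays alone and 1543 with array weights. The difference of 5′ and 3′ control probe sets went from 0.03 ± 0.11 (SD) on +Fe to -0.14 ± 0.08 on -Fe in mutant leaves, and was 0.07 on both media in Col leaves. Between genotypes, 27 probe sets rose in both, against 0.143 for independent calls, and 35 fell in both, against 0.251. Across probe sets the responses correlated at r = 0.52 (Spearman's rho 0.27), and 90.4% of the 198 called in either genotype had the same sign.

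The genotype by iron interaction in leaves had 0 calls with limma, with 910 probe sets at an unadjusted p under 0.05. The 5 named genes with the smallest p had interactions of -0.82 ± 0.15 (CDI), -1.05 ± 0.2 (AT1G57650), 0.83 ± 0.16 (AT4G27290), 1.4 ± 0.29 (AT5G58660) and -1.24 ± 0.27 (AT4G39830), with adjusted p from 0.562 to 0.853. The interaction of BHLH101 was -1.61 ± 0.42 and that of BTSL1 -0.71 ± 0.17; both passed only when adjusted over their lists alone, 1 of 7 iron regulators and 1 of 5 iron acquisition genes. The auxin list moved down at adjusted p = 0.049, lost at adjusted p = 0.29 with an estimated correlation and at 0.054 after quantile normalization; 0 of its 6 genes passed by limma, over all probe sets or over the list alone. The tetrapyrrole list moved down only after quantile normalization (adjusted p = 0.029, and 0.058 as given). A fit of all 24 arrays gave 4 calls, array weights 5 and a block for number within genotype 2. AT1G57650 passed with array weights (-1.09, adjusted p = 0.0331).

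In leaves on +Fe, CML41, a calmodulin-like gene, was 5.51-fold higher in the mutant (log2 2.46 ± 0.26, n = 3 per group, adjusted p = 0.000364). XTH19, a cell wall xyloglucan endotransglucosylase gene, was higher by 4.99-fold (log2 2.32 ± 0.24) and AT3G28580, of the AAA-type ATPase family, by 5.41-fold (log2 2.44 ± 0.3). AT2G33850 was lower by 7.68-fold (log2 -2.94 ± 0.34), AT5G26270 by 4.86-fold (log2 -2.28 ± 0.35) and AT5G33370, of the GDSL lipase family, by 4.72-fold (log2 -2.24 ± 0.26). RGLG5, of the same ligase family as the mutated genes, was higher by 0.75 ± 0.2 (adjusted p = 0.027). Of 7 tetrapyrrole genes HEME1 (-0.58 ± 0.14) and HEME2 (-0.41 ± 0.12) were lower, and 5 when adjusted over the list alone. The list moved down at adjusted p = 0.011, lost at adjusted p = 0.36 with an estimated correlation and at 0.061 after quantile normalization. BTSL2 was higher by 0.67 ± 0.19, the 1 call among 5 iron acquisition genes, and GH3.3 by 0.92 ± 0.28, the 1 call among 6 auxin genes, each also when adjusted over its list alone. In the abscisic acid and dehydration list 3 of 3 were lower only when adjusted over the list alone.

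In all 2557 probe sets differed, 1278 higher and 1279 lower. The count was 3866 without mutant +Fe replicate 3, 925 and 974 without mutant +Fe replicates 1 and 2, and 1078, 1019 and 1598 without Col +Fe replicates 1, 2 and 3. It was 8248 with array weights and 5670 without replicate 3 of the mutant leaves on both media.

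On -Fe, AT3G28580 was 4.86-fold higher in mutant leaves (log2 2.28 ± 0.3, n = 3 per group, adjusted p = 0.00114) and CML41 4.07-fold higher (log2 2.02 ± 0.26). AT2G33850 was lower by 7.72-fold (log2 -2.95 ± 0.34) and AT5G26270 by 6.17-fold (log2 -2.63 ± 0.35). BHLH101 was lower by 3.97-fold (log2 -1.99 ± 0.3, adjusted p = 0.00216), the 1 call among 7 iron regulators, and BTSL1 was lower by 0.78 ± 0.12, the 1 call among 5 iron acquisition genes, each also when adjusted over its list alone. Of 7 tetrapyrrole genes 5 were lower, among them HEME1 (-1.03 ± 0.14), CHLI2 (-0.69 ± 0.16), CHLM (-0.56 ± 0.15) and HEME2 (-0.52 ± 0.12), and all 7 when adjusted over the list alone. The list moved down at adjusted p = 3e-04, lost at adjusted p = 0.26 with an estimated correlation. Of 6 auxin genes IAA29 (-1.31 ± 0.38) and GH3.5 (-0.5 ± 0.14) were lower, and of 8 photosynthesis genes LHCB4.2 (-0.49 ± 0.14), with the same counts adjusted over the lists alone. COR15A (-0.71 ± 0.21) was lower, 1 of 3 in the abscisic acid and dehydration list, and 3 of 3 when adjusted over the list alone.

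In all 2840 probe sets differed, 1100 higher (38.7%) and 1740 lower. The count was 4772 without mutant -Fe replicate 3, 1450 and 1240 without mutant -Fe replicates 1 and 2, and 1541 and 1118 without Col -Fe replicates 1 and 2. It was 1576 with the 6 arrays alone, 6628 with array weights, and 5751 without replicate 3 of the mutant leaves on both media. The difference of 5′ and 3′ control probe sets averaged -0.14 ± 0.08 (SD) in mutant leaves on -Fe and 0.07 ± 0.04 in Col leaves on -Fe. The array median of mutant -Fe replicate 3 was -0.136. The differences on +Fe and -Fe shared 553 probe sets that were higher, against 78.9 for independent calls, and 799 that were lower, against 125, with r = 0.82 (Spearman's rho 0.76) across probe sets.

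**Figure D4:**
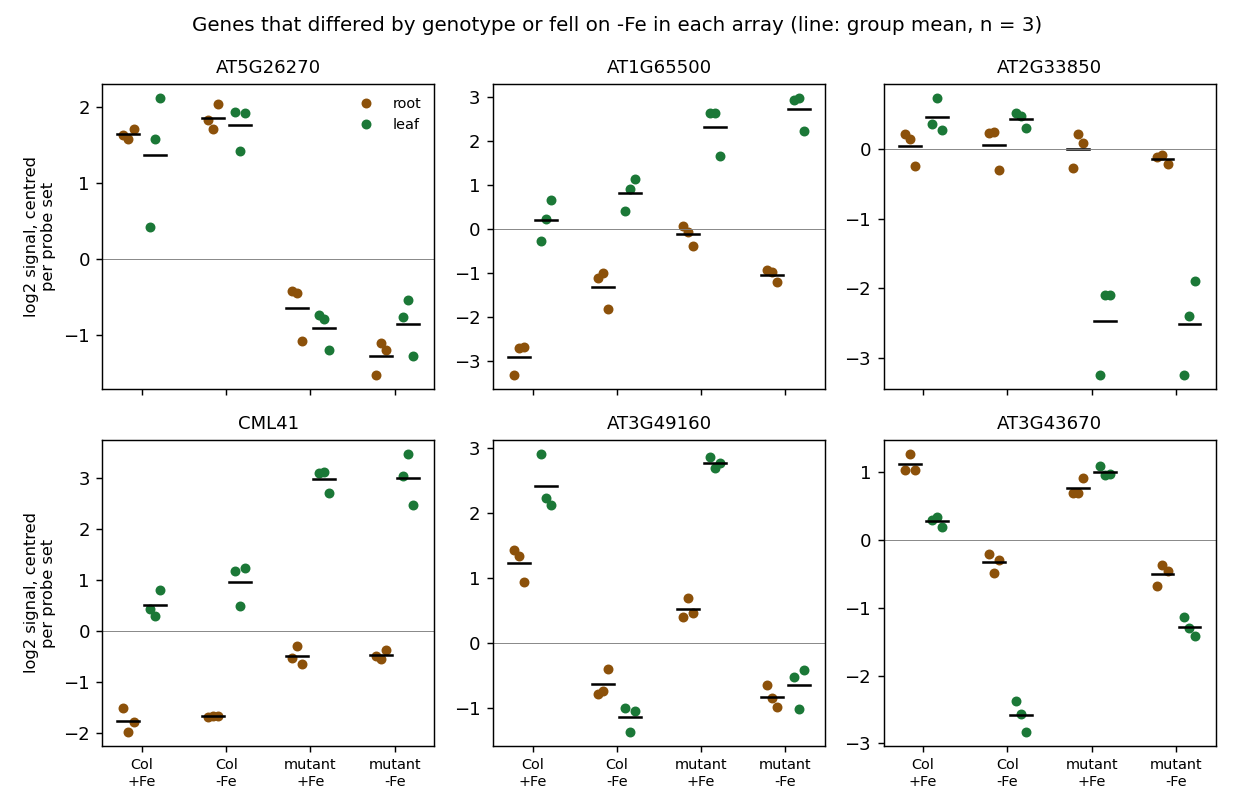
Centred log2 signal of 6 genes in each of the 24 arrays, by genotype and medium (roots brown, leaves green, line at the mean of 3 arrays). AT5G26270 lies at -0.42 or below in all mutant arrays and at 0.42 or above in all Col arrays.

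Across both tissues and media, 49 probe sets were higher and 42 lower in the mutant in all 4 genotype comparisons, against 0.082 and 0.13 for independent calls. The comparisons within a tissue share a variance estimate and are not independent, so these numbers are no test. A single gene was named for 29 and 18 of them. AT5G26270 had the largest fall among the named genes, with differences of -2.29, -3.14, -2.28 and -2.63. The unnamed 259178_at (-3.65, -3.95, -2.4 and -2.58) and 250177_at (-2.91, -3.14, -0.75 and -1.24) were lower in all 4 as well. Root and leaf differences between genotypes correlated only weakly across probe sets, with r = 0.18 on +Fe and 0.19 on -Fe.

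The tissue by iron interaction tested where the iron response of Col leaves differed from that of Col roots. S8H (-5.21 ± 0.21, n = 3 per group, adjusted p = 1.1e-12), MTP8 (-4.04 ± 0.17) and BGLU42 (-2.58 ± 0.19) responded far less in leaves. AT4G36700 (4.74 ± 0.59), AT3G02480 (4.27 ± 0.4), BHLH101 (2.25 ± 0.38) and IMA1 (2.13 ± 0.45) responded more in leaves. SAPX had an interaction of -2.41 ± 0.26. S8H and BGLU42 were the calls in the iron acquisition list of 5 (4 lower when adjusted over the list alone) and in the phenylpropanoid and coumarin list of 5 (3 when adjusted over the list alone). These lists moved down (adjusted p = 5.1e-11 and 5.2e-09, and adjusted p = 0.0088 for each with an estimated correlation). Of 7 iron regulators BHLH101 and IMA1 were called, and 3 when adjusted over the list alone, with a set shift up at adjusted p = 0.062. RCA (0.94 ± 0.19) and PSBY (0.63 ± 0.16) were called among 8 photosynthesis genes, and 3 higher and 1 lower when adjusted over the list alone. The photosynthesis list moved up at adjusted p = 0.042, lost at adjusted p = 0.45 with an estimated correlation and at 0.19 after quantile normalization. GH3.5 (0.9 ± 0.18) was the 1 call among 6 auxin genes, also when adjusted over the list alone; the list moved up at adjusted p = 0.0088, lost at adjusted p = 0.13 with an estimated correlation.

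In all 311 probe sets differed in response, 139 more positive and 172 more negative in leaves. The count was 936 with array weights, 664 without replicate 3 of the mutant leaves, which share the fit, and 204 without root Col -Fe replicate 2. The iron responses of Col roots and leaves shared 35 probe sets that rose, against 2 for independent calls, and 33 that fell, against 2.76, with r = 0.27 (Spearman's rho 0.2) across probe sets.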

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

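The tests of Col RNA, of a shared day and of root tissue as the cause of the shift of replicate number 3, and the comparisons of its root-specific and its 5′ and 3′ control probe sets with replicates 1 and 2, were chosen after the result was seen. So were the fits without replicate 3 of the mutant leaves.

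The interaction tests called these genes for a different iron response between genotypes or tissues. For the 3 in roots, each call was lost without some single arrays. The splits below do not exclude chance for the genotype or the tissue interaction. In roots, the response in the mutant minus that in Col was -2.5 for AT1G65500, -1.44 for AT4G15690 and -1.31 for AT3G46880. In Col, the response in leaves minus that in roots was 4.74 for AT4G36700, 4.27 for AT3G02480, 3.45 for AT1G52820, 2.83 for AT1G12030 and 2.25 for BHLH101. It was 2.19 for UGT76B1, 2.13 for IMA1, 2.1 for AT3G13840, 1.59 for AT5G01740 and 1.56 for AT3G01175. The most negative values were -5.21 for S8H, -4.19 for AT3G61930, -4.04 for MTP8, -3.54 for AT3G07720 and -3.4 for AT4G19370. They were -3.34 for AT5G38820, -2.68 for AT5G04730, -2.58 for BGLU42, -2.41 for SAPX and -2.39 for FOLB1.

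Other splits of the arrays were counted for each comparison. For the comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05, and 1 split of 10, the real one, reached the real count in each. Among the iron responses, Col roots had 921 real calls and at most 14 in another split, mutant roots 1266 and 0, Col leaves 184 and 0, and mutant leaves 76 and 7. Among the genotype differences, roots had 1913 and 0 on +Fe and 693 and 0 on -Fe, and leaves had 2557 and 57 on +Fe and 2840 and 0 on -Fe. For the interaction in roots, 5 of 100 splits gave at least the real count of 3, so the splits do not exclude chance. The 4 others, with 63, 26, 16 and 4 calls, each kept all 6 genotype labels on 1 medium and 2 of the 6 on the other. They carry the genotype difference and point to a structure of the samples, so they do not measure chance either. For the interaction in leaves, the real count was 0, which 100 of 100 splits reach whatever the data, so the splits say nothing about it; the highest other split, with 1257, had the same structure. For the tissue by iron interaction, 2 of 100 splits reached the real count of 311, the real one among them. The other gave 823, kept all labels in leaves and 0 of 6 in roots, and so measured the sum of both iron responses. The next highest, with 260, 221, 191 and 189 calls, each kept or reversed all labels of 1 tissue. Such splits carry iron responses and do not measure chance, so they do not exclude it here either.

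Replicate 3 of the mutant leaves lay between the other mutant arrays and Col on the main leaf axis on both media, and no biological explanation of this was tested. On the second leaf axis its -Fe array, at 5.5, lay between the other -Fe arrays (-24.8 to -12.1) and the +Fe arrays (11.9 to 18.5). On the main axis of the leaf arrays, Col number 3 in turn lay nearest to the mutant among the Col arrays. It was at -26.7 on +Fe (others -41.6 and -37.7) and -11.2 on -Fe (others -23.1 and -28). In leaves, number 3 thus had a smaller gap between genotypes from both sides, and such opposite shifts give negative correlations between the genotypes. In roots too, number 3 lay nearest to the other genotype in all 4 groups on the second axis. A shared day acting alike on both genotypes is argued against as the cause of these opposite leaf shifts. The deviations of the Col and mutant leaf arrays of number 3 from their group means correlated negatively, at -0.28 at most. As the opposite shifts weigh on this correlation, it cannot exclude a shared effect apart from them. Number 3 had the lowest 5′ minus 3′ control difference in all 4 leaf groups (0.01 and 0.02 in Col, -0.07 and -0.22 in the mutant) and the highest in all 4 root groups. A handling of number 3 thus stays open, as a shared effect apart from these shifts or as one that acted differently on the genotypes. Col RNA was not decided by the probe sets low in mutant roots, with median shares kept of 0.87 (7 probe sets on +Fe) and 0.78 (5 on -Fe) and lowest shares of 0.07 and -0.01, but as the only cause it is argued against: it would give 1 share of Col signal to all probe sets, whereas the medians were 0.12 and 0.16 for those at least 2 log2 lower in the mutant and 0.79 and 0.96 for those at least 2 log2 higher (0.36, 0.29, 0.68 and 0.86 from 1 log2). Root tissue was not decided by the median of 50 root-specific probe sets, which was -3.38 on +Fe, above Col leaves (-3.65 to -3.43), and -3.55 on -Fe, but as the cause it is argued against: number 3 differed from replicates 1 and 2 by -0.06 and -0.23, and the highest root share over the lowest leaf array (0.35%) could give at most 1.2% of the median shift of number 3.

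In mutant leaves on -Fe, more probe sets were lower (1740) than higher (1100, 38.7%) against Col. After centring each array on its median the share that was higher was 47.8% (1437 higher and 1568 lower), but centring itself moves the balance towards equal numbers, so this does not show whether scaling between arrays caused the split. Without replicate 3 of the mutant leaves on both media the split was 2882 higher and 2869 lower. Without mutant -Fe replicate 3 alone, 51.8% were higher. The share was 36.2% and 32.2% without mutant -Fe replicates 1 and 2, and 33.2% and 39% without Col -Fe replicates 1 and 2. The excess of lower probe sets thus rested on mutant -Fe replicate 3, whose array median was -0.136, and cannot be read as an effect of genotype. Whether scaling of that array gave it stays open.

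The iron response had 76 calls in mutant leaves and 184 in Col leaves, while the interaction test had 0 calls with limma (910 at an unadjusted p under 0.05). The counts were 38 and 319 with the arrays of each genotype alone, 1543 and 766 with array weights, and 166 in the mutant without mutant -Fe replicate 3. A larger spread between mutant leaf arrays, with a median SD 1.3 times that in Col leaves (0.196 against 0.151), could lower the count, but the fit shares 1 variance between the genotypes, so the spread falls on both counts; without replicate 3 the counts were 111 and 565, farther apart, though with 2 mutant arrays per group against 3 of Col. A smaller response in mutant leaves is a biological explanation: over 313 probe sets chosen by the mean response of both genotypes, the median ratio of mutant to Col change was 0.79, and 73.2% changed less in the mutant. With 1 array left out the probe sets were chosen anew. Without mutant -Fe replicate 3 the median ratio was 1.03, over 921 probe sets. With any other single array left out it was 0.74 to 0.83, over 176 to 264 probe sets. The upper end thus rested on 1 array, which lay between the other -Fe arrays and the +Fe arrays on the second leaf axis. The explanations cannot be told apart.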

How the results depend on the processing

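The block for number within genotype and the fits without replicate 3 of the mutant leaves were chosen after the data were seen. Named-gene values were not tallied for the fits with other sets of arrays or for the trend and robust prior. Whether the named calls held under those settings was not tested. Of the values for 188 named-gene results under the other alternatives, 2168 kept direction and side of the threshold. Another 72 lost the call, 1 gained it and 0 changed direction. Of the losses 71 came from leaving out 1 array and 1 from quantile normalization (AT1G49010, mutant leaves, -1.17, adjusted p = 0.0561).

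With only the arrays compared in the fit, the iron response had 602 calls in Col roots, 319 in Col leaves and 38 in mutant leaves, and the genotype difference 812 (+Fe) and 1106 (-Fe) in roots and 1576 in leaves on -Fe. The cause was not tested. With all 24 arrays in the fit, the leaf interaction had 4. With array weights, calls were 1578 and 5097 for the root iron response in Col and mutant, 393 for its interaction, 5634 and 1921 for the root genotype difference on +Fe and -Fe, 766 and 1543 for the leaf iron response in Col and mutant, 5 for its interaction, 8248 and 6628 for the leaf genotype difference, and 936 for the tissue interaction; the cause was not tested. The block within genotype gave 7 (root interaction), 539 (Col leaves) and 2 (leaf interaction). Without replicate 3 of the mutant leaves the counts were 565 (Col leaves), 5670 and 5751 (leaf genotype difference on +Fe and -Fe) and 664 (tissue interaction); the cause was not tested. With an estimated correlation 11 of 25 gene list shifts passed. The list tests were not repeated with single arrays left out.

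Replicate number as a block, the trend and robust prior, quantile normalization and median centring moved no count by over 1.5 times. Outside the mutant leaf iron response, the rule for pairing by number was not met, which does not exclude a link by number. Between media the correlations were 0.34, 0.05 and 0.2 in Col leaves, 0.17, -0.08 and 0.42 in Col roots, and 0, 0.05 and 0 in mutant roots. Between genotypes they lay from -0.29 to 0.13. With the block, the iron response had 934 calls in Col roots, 1298 in mutant roots and 187 in Col leaves. The genotype difference had 1862 and 670 in roots and 2551 and 2896 in leaves. Interactions had 4 in roots, 0 in leaves and 332 between tissues.

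With 1 array left out, the root iron response ranged from 612 to 1108 in Col and from 592 to 3315 in the mutant, and its interaction from 0 to 387. The root genotype difference ranged from 728 to 3758 (+Fe) and 257 to 502 (-Fe). The leaf iron response ranged from 90 to 163 in Col and from 50 to 166 in the mutant, and its interaction stayed at 0. The leaf genotype difference ranged from 925 to 3866 (+Fe) and 1118 to 4772 (-Fe), and the tissue interaction from 204 to 309. Shared iron calls ranged from 354 to 584 in roots and 48 to 93 in leaves. The highest values came without mutant replicate 3 of the comparison concerned for 3315, 387, 3758, 166, 3866 and 4772. A filter on dim probe sets was not run, because the values hold no absolute signal, so the limit set by signal over background is unknown.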

Other observations

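The gene families were chosen after the data were seen, while the test of an iron-deficiency-like state was set before its result was seen.

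Beyond the main lists, several families held members that changed with iron or genotype. In roots on -Fe, UGT72E1 (log2 2.55 ± 0.14 in Col and 2.7 ± 0.14 in the mutant, n = 3 per group), a UDP-glycosyltransferase, and CYP71B5 (2.02 ± 0.22 and 2.47 ± 0.22), a cytochrome P450, rose. So did PUB23 (1.51 ± 0.13 and 1.45 ± 0.13), a U-box ubiquitin ligase, and scpl20 (0.8 ± 0.11 and 1.32 ± 0.11). Of 40 measured UDP-glycosyltransferases, 2 rose and 5 fell in Col roots, and 2 rose and 2 fell in mutant roots. Of 10 SWEET sugar transporters, 4 were lower in mutant leaves on -Fe, among them SWEET4 (-1.09 ± 0.14) and SWEET2 (-0.72 ± 0.18). In mutant roots on +Fe, SWEET13 (0.72 ± 0.08), SWEET14 (0.77 ± 0.13) and SWEET16 (0.49 ± 0.13) were higher and SWEET11 (-0.96 ± 0.25) lower. The cell wall genes XTH19 (2.32 ± 0.24), XTH18 (1.59 ± 0.4) and XTH33 (1.08 ± 0.27) were higher in mutant leaves on +Fe, 3 of 8 xyloglucan endotransglucosylases. In the same comparison CYP71B36 (1.82 ± 0.12) was higher and CYP71B22 (-1.64 ± 0.2) lower.

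As sets, the 67 plastid-encoded genes moved down on -Fe in Col roots (median -0.2, adjusted p = 0.00037, lost at adjusted p = 0.75 with an estimated correlation) and in Col leaves (median -0.3, adjusted p = 0.00059, lost at adjusted p = 0.86 with an estimated correlation). The medians were -0.06 and -0.24 after quantile normalization and -0.23 and -0.32 after median centring. No single plastid-encoded gene was called by limma in Col leaves, where the smallest adjusted p was 0.26 (rpl16). The 11 ubiquitin-conjugating enzymes moved up on -Fe in mutant leaves (median 0.2, adjusted p = 0.017), and the SWEET transporters moved down in mutant leaves on +Fe (median -0.41, adjusted p = 0.043). Both calls were lost at adjusted p = 0.75 with an estimated correlation. On the values as given, with the preset correlation, no other family moved as a set over the 143 tests.

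Lists with 1 or 2 measured genes were read gene by gene. The copper chaperone gene CCS rose on -Fe in Col roots (0.41 ± 0.09) and mutant roots (0.56 ± 0.09). The zinc transporter gene ZIP9 also rose, by 0.55 ± 0.11 and 0.49 ± 0.11. HCF101, of plastid iron-sulfur assembly, was at -0.37 ± 0.1 in mutant roots (adjusted p = 0.04) and close to that in Col roots, at -0.32 ± 0.1 (adjusted p = 0.089). The clock gene GI rose by 0.51 ± 0.12 in Col roots, and its value in mutant roots was -0.04 ± 0.12; the interaction did not pass over all probe sets (-0.55 ± 0.17, adjusted p = 0.51). Values for the heat shock gene HSP17.6C (-0.62 ± 0.43), the jasmonate marker PDF1.2 (-0.08 ± 0.2) and the touch-responsive ZAT10 (0.21 ± 0.34) in Col roots did not pass. Of the 4 root hair and epidermal patterning genes, 0 were called by limma in any comparison, and the list did not move (adjusted p = 0.56 in Col roots).

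A hypothesis was that mutant roots on +Fe may be in a state like iron deficiency. It was tested on probe sets that responded to iron in Col by a log2 change of at least 1, with the Col arrays split so that none served for both the response and the genotype difference. In each split the response was taken against 1 Col +Fe array, and the probe sets did not have to be called. The median genotype difference along the response was 0.27, 0.19 and 0.11 in the 3 splits, with a mean of 0.19, against 0.06, 0.04 and -0.01 for other probe sets. The mean was positive but did not exceed the 0.2 that the hypothesis called for, so the test left it open. Among genes that rose on -Fe in Col roots, S8H (0.14 ± 0.16), MTP8 (-0.23 ± 0.12) and BHLH101 (-0.04 ± 0.18) were not called between genotypes on +Fe. IMA1 was higher in the mutant (1 ± 0.21). The iron acquisition and iron regulator lists did not move in that comparison (camera, adjusted p = 0.65 and 0.27).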
